A study of Micropterus salmoides with 16 samples.

How the data were processed

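Total RNA of whole ovary from female largemouth bass was labelled with Cy3 and hybridised to 1-colour Agilent arrays, with 16 arrays in 4 groups of 4 (control, methoxychlor, p,p'-DDE and flutamide). Groups were taken from the labels. The design text calls the samples biological replicates and does not say whether an array held the ovary of 1 fish. Replicates were numbered in deposition order within a group, so a number only names a sample and pairs nothing. Doses, the length of exposure and the stage of the ovaries were not given in the sources used here.

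The scanner files hold spot intensity values made with Agilent Feature Extraction 10.1.1.1, per the file headers, which record local background subtraction, spatial and multiplicative detrending and surrogate values for dim spots. The deposited processed intensity was not normalised between arrays. The authors' deposited value table holds log2 values. Its columns correlated with the log2 processed signal of their own array at 0.996 or more, and the column medians lay between 9.09 and 9.11, so the arrays had been brought to nearly one distribution. The method behind that table was not given in the sources used here. Its direction and log scale were settled by this comparison, and its exact centring stays unknown. Within an array the table kept the order of probes (Spearman rho with the processed signal at least 0.99998). With nearly one distribution as well, its results and those of quantile normalisation are not separate checks.

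An array held 15744 spots, of which 15208 were probes of 60 bases and 536 were controls. The signal was log2 of the processed intensity minus the 75th percentile of that array. Control spots and the 122 probe spots marked as outliers over all arrays were left out, and no probe spot was saturated. A probe was tested if it was well above background on all arrays of at least 1 group, which kept 14109 probes and left out 1099. Each probe was fitted over all 16 arrays at once with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, without a covariate, and 2-sided p-values were adjusted by the Benjamini-Hochberg method within a comparison. The threshold was an adjusted p of 0.05. The number of arrays and the spread between them limit the precision: the median standard error of a log2 fold change was 0.32. At the median, a 95% interval reached 0.67 to either side on the log2 scale, or 1.59-fold.

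The arrays lay on 2 slides, each scanned as a batch. Slide 1 held 2 control, 2 methoxychlor, 3 DDE and 1 flutamide arrays, and slide 2 held 2 control, 2 methoxychlor, 1 DDE and 3 flutamide arrays. Slide was tested as a fixed block, as a random block and within each slide. The other alternatives were normexp background correction with an offset of 50, quantile normalisation, median scaling, the authors' value table, no filter on dim probes, a filter that asked for all 16 arrays, only the compared groups, an intensity trend with robust moderation, array quality weights, an adjusted p of 0.1, and leaving out each replicate in turn. The groups, tests and these alternatives were fixed before the data were examined. Array brightness as a covariate was added after seeing the data.

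The fits were tested on simulated data for DDE against control, with 200 of 14007 probes changed in each of 10 draws and the residuals of these arrays as noise. At an adjusted p of 0.05, 22.8% of probes changed 2-fold, 78.4% of those changed 4-fold and 94.2% of those changed 8-fold were recovered. At 2-fold the share ran from 10.45% to 38.81% over the draws. The median number of unchanged probes called was 0, and the highest in a draw was 47. The residuals were shuffled over the arrays, so any link between brightness and group was not kept. With independent noise of SD 0.2 in place of the residuals, 100% were recovered at each fold.

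The scanner files give 0 probes a description other than unknown, and 0 of the probe identifiers matched the reference table of 37622 genes. The 20 gene lists, the panel of reproductive genes, the cell type markers and the rule for named genes fixed beforehand could therefore not be applied, and no probe is given a gene name. In place of genes, probes are reported by identifier, at most 2 higher and 2 lower for a comparison: those with the smallest unadjusted p among probes with an absolute log2 fold change of at least 0.58. This use of unnamed probes was chosen after the values were seen. A probe that was not well above background on any array of a group has only a bound there. Its fold is given as at least the brighter group's mean over the mean, per array, of the higher of the lowest signal among probes well above background and its own signal.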

Results

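Gene expression was measured in whole ovary of largemouth bass (Micropterus salmoides) after dietary exposure to 2 organochlorine compounds, methoxychlor and p,p'-DDE, with a flutamide group and a control group. Methoxychlor is a pesticide and p,p'-DDE is a persistent breakdown product of the pesticide DDT. Flutamide is a drug that blocks the androgen receptor. Each of the 4 groups had 4 biological replicates, with 1 array per replicate. Every comparison asked which transcripts differed in level between the groups. The 60-base probes carried contig identifiers and no gene names, so levels are given by probe.

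Arrays differed in brightness. The 75th percentile of the processed signal averaged 2393 ± 1056 (SD, n = 4) in controls, 2141 ± 911 in methoxychlor, 5373 ± 2291 in DDE and 3782 ± 1545 in flutamide. Between 89.5% and 97.2% of probes were well above background on an array. On the log2 scale the DDE arrays were brighter than the control arrays by 1.13, with an exact permutation p of 0.0857 (2-sided, adjusted p = 0.462 over 30 comparisons of array measures). After scaling, arrays correlated over probes at 0.918 to 0.988. The mean correlation was 0.967 within groups and 0.964 between groups. The first principal component held 36.2% of the variance and the second 19.7%. Scores on the first correlated with log2 brightness over the 16 arrays (Pearson r = -0.90, permutation p = 2e-05; Spearman rho = -0.88, permutation p = 3e-05). Without the 2 arrays of most extreme brightness r was -0.86. The relation held within slide 1 (r = -0.88, exact permutation p = 0.00216) and within slide 2 (r = -0.94, exact permutation p = 0.00062). It was 1 of 3 relations examined, with an adjusted p of 6e-05.

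**Figure D1:**
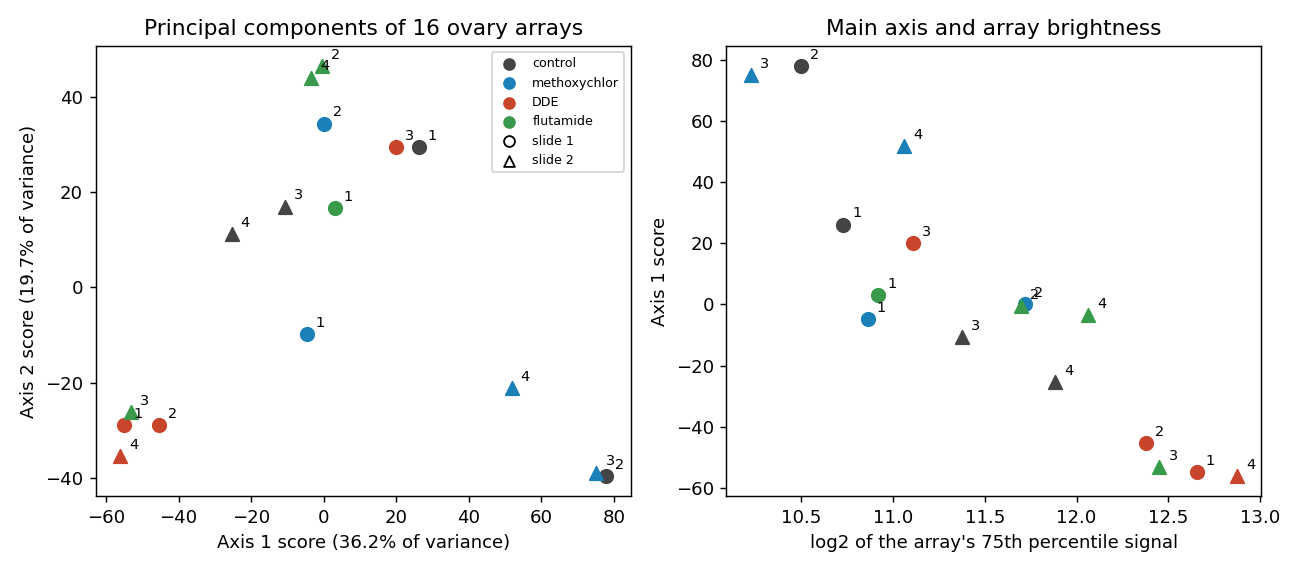
The left panel plots each array's scores on the first and second principal components of log2 signals, and the right panel plots the first score against log2 of the array's 75th percentile signal. Colours give the group, symbols the slide and digits the replicate; DDE replicates 1, 2 and 4 and flutamide replicate 3 lie between -56.1 and -45.5 on the first axis, and DDE replicate 3 lies at 20.04.

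In ovaries of methoxychlor-exposed fish, the probe UF_Msa_CF_119983 read 0.85 higher than in controls on the log2 scale (SE 0.18; limma adjusted p = 0.455; n = 4 per group). UF_Msa_CF_124455 read 1.38 higher (SE 0.34, adjusted p = 0.54). Lower readings with the smallest p were those of UF_Msa_CF_124914 (log2 fold change -1.19, SE 0.22, adjusted p = 0.455) and UF_Msa_AF_107533 (-1.38, SE 0.27, adjusted p = 0.455). UF_Msa_AF_107533 also read -4.01 to -3.29 in flutamide, below all controls at -2.95 to -2.14. In DDE it read -3.99 to -2.78, overlapping the controls. UF_Msa_CF_119983 read 1.58 to 1.98 in flutamide and 1.35 to 1.98 in DDE, against 1.25 to 1.44 in controls. The direction for both was thus not particular to methoxychlor. With normexp background correction UF_Msa_CF_124914 turned to 0.82 and UF_Msa_AF_107533 shrank to -0.20. UF_Msa_CF_124914 was dim, with a processed signal of 7.9 to 25.6 in methoxychlor and 32.7 to 49.1 in controls, below the normexp offset of 50. Normexp also moved the median log2 fold change of all probes from 0.05 to 0.40. None of the named probes passed the threshold. By limma, 0 of 14109 probes passed at an adjusted p of 0.05, and 332 had an unadjusted p below 0.05, of which 113 were higher and 219 lower, where chance alone gives about 705. That balance had no settled direction: normexp gave 281 higher of 312, array quality weights 822 of 1084, and leaving out control replicate 2 gave 1022 of 1258. Without methoxychlor replicate 2 the count was 532. The 95% interval lay within 2-fold either way for 63.5% of probes. On slide 2 alone 801 probes passed, 774 of them higher, and 0 did on slide 1 alone or with slide as a block. The methoxychlor arrays of slide 2, replicates 3 and 4, scored 75.2 and 51.9 on the first axis, against -4.69 and 0.10 for replicates 1 and 2. Their spike-in signals of 10.58 and 11.42 on the log2 scale were the lowest of the 16 arrays, and replicate 3 had the lowest 75th percentile, 1197. Control replicate 2, on slide 1, had the highest score on the first axis, 77.98. Its spike-in signal was 11.60 and its 75th percentile 1448. Slide 2 alone does not hold that control array. Whether the difference between the slides rests on it or on the methoxychlor arrays was not tested.

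In ovaries of DDE-exposed fish, UF_Msa_AF_108602 was not well above background on any of the 4 arrays and was well above it on all 4 control arrays. It was also not well above background on methoxychlor replicates 3 and 4 of slide 2, at -8.72 and -10.05. With the chosen background treatment its level in DDE was at least 11.6-fold lower than in controls (limma adjusted p = 0.165). The log2 fold change was -5.26, and -2.06 with normexp background correction, so the fold and its bound rest on how background was treated. Its sequence is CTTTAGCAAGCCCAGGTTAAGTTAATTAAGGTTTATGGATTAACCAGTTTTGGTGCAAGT. UF_Msa_CF_123486, with the sequence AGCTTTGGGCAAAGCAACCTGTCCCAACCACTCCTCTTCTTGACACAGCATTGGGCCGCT, averaged -3.54 ± 2.18 in DDE and 0.18 ± 0.59 in controls on the scaled log2 scale (SD, n = 4; log2 fold change -3.72, limma adjusted p = 0.389). DDE replicate 2 read -0.27 and the other DDE arrays -4.82 to -4.51. Without that replicate the limma adjusted p was 3.25e-05, but the array left out was the only DDE array within the control range. The probe was also picked from these data, so that p is no separate support for a difference. Higher readings were those of UF_Msa_AF_110254 (log2 fold change 1.04, SE 0.22) and UF_Msa_AF_102504 (1.77, SE 0.37), each with an adjusted p of 0.389. With normexp UF_Msa_AF_102504 fell to 0.46. Without DDE replicate 3 these 4 probes each had an adjusted p of 0.045, and with array quality weights 0.00371 to 0.00729. The probes were picked for a small p in the same data. The weights were 0.244 for DDE replicate 3 and 2.14 to 3.51 for the other DDE arrays, so they repeat much of that omission. These smaller p-values are therefore not 2 separate supports. By limma, 0 probes passed at an adjusted p of 0.05. At an unadjusted p below 0.05 there were 1776, 952 higher and 824 lower. The balance turned with the scaling, to 614 higher of 2027 with median scaling and 207 of 632 with normexp. With brightness as a covariate, an alternative chosen after seeing the data, the count was 256, with 160 higher, and on slide 2 alone it was 463. The count without 1 array was 772, 718, 4474 and 562 for DDE replicates 1, 2, 3 and 4, and 808 and 904 for control replicates 1 and 2. Without DDE replicate 3, 1114 probes passed, 659 higher and 455 lower, and with array quality weights 4445 passed. With all 16 arrays and slide as a block 0 passed, as on slide 1 alone. Slide 2 holds only 1 DDE array. Without DDE replicate 3 and with slide as a block, 912 passed.

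In ovaries of flutamide-exposed fish, UF_Msa_CF_125164 read -5.33 ± 0.79 against -2.62 ± 0.27 in controls (SD, n = 4), a log2 fold change of -2.70 (SE 0.44, limma adjusted p = 0.166). The probe also read -5.39 to -3.72 in methoxychlor and -5.19 to -3.41 in DDE, against -2.97 to -2.36 in controls. It was thus not low in flutamide alone. Its sequence is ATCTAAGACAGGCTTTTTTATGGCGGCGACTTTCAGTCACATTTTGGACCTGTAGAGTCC. UF_Msa_AF_103045 had a log2 fold change of -1.40 (SE 0.25, adjusted p = 0.166). UF_Msa_AD_200085 averaged 4.25 higher (SE 1.19, adjusted p = 0.501), from 3 arrays at -1.73 to -0.76 and flutamide replicate 4 at -6.99. DDE replicate 1 also read high, at -1.95. UF_Msa_CF_125011 read 1.31 higher (SE 0.34, adjusted p = 0.395). With normexp these last 2 values were 2.49 and 0.19. By limma, 0 probes passed at an adjusted p of 0.05, and 735 had an unadjusted p below 0.05, 260 higher and 475 lower. The excess of lower probes was absent with other scalings: 352 of 677 were higher with quantile normalisation, 329 of 644 with median scaling and 349 of 673 in the authors' value table. Normexp gave 202, with 88 higher. The count was 425 without control replicate 2, 446 without flutamide replicate 4 and 1207 without control replicate 4. Leaving out control replicate 4 let 1 probe pass, as did slide 2 alone.

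**Figure D2:**
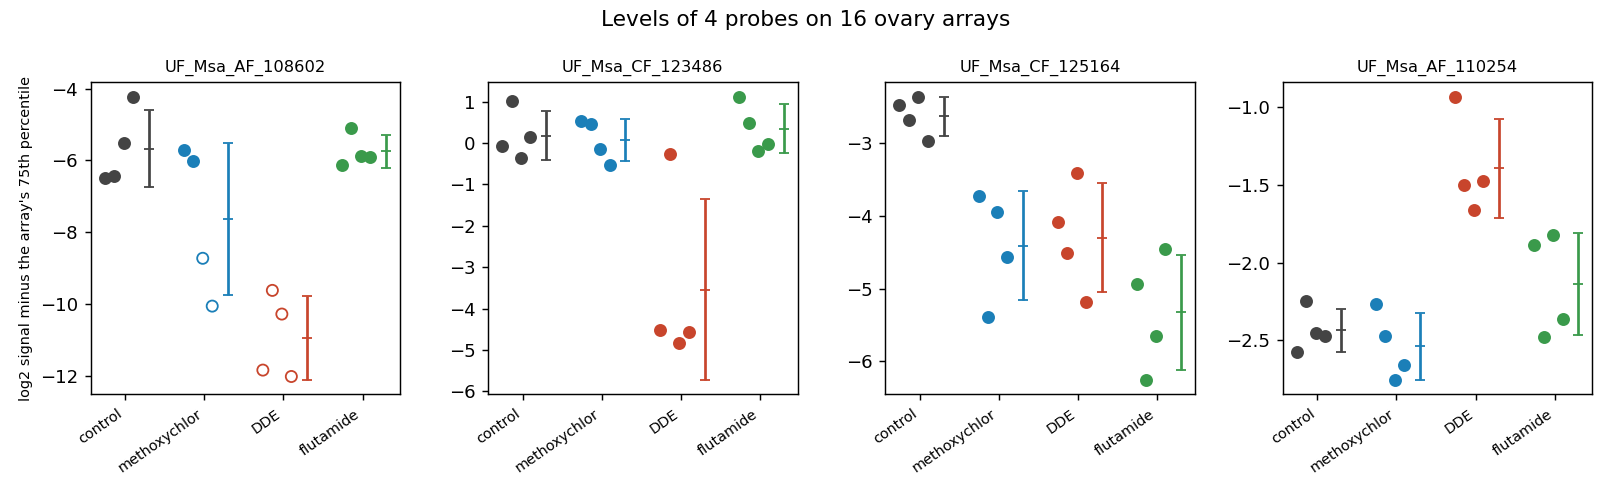
Log2 signal minus the array's 75th percentile is plotted for 4 probes on all 16 arrays, by group; filled points were well above background, open points were not, and bars give the mean and SD of 4 arrays. UF_Msa_AF_108602 was not well above background on any DDE array, and UF_Msa_CF_123486 was low on 3 DDE arrays and at -0.27 on DDE replicate 2.

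Methoxychlor and p,p'-DDE are both relatives of DDT. Methoxychlor carries methoxy groups in place of the ring chlorines, and DDE has lost hydrogen chloride from its ethane bridge. Doses were not given in the sources used here, so whether they matched is unknown. Between these compounds UF_Msa_AF_105185 read 2.25 higher in DDE (SE 0.42, 95% interval 1.36 to 3.14, limma adjusted p = 0.28), and UF_Msa_AF_110254 read 1.15 higher (SE 0.22, adjusted p = 0.28). With normexp these were 1.01 and 0.64. UF_Msa_CF_123486 differed by -3.62 (95% interval -5.22 to -2.03, adjusted p = 0.28) and UF_Msa_AF_100046 by -1.38 (SE 0.30, adjusted p = 0.28). By limma, 0 probes passed, and 2430 had an unadjusted p below 0.05, 1001 higher and 1429 lower in DDE. Median scaling gave 681 higher of 2841 and normexp 125 of 4639. With brightness as a covariate the count was 247, with 154 higher in DDE, and on slide 1 alone it was 215, with 153 higher. The count without 1 array was 1076, 1221, 4853 and 1077 for DDE replicates 1, 2, 3 and 4, and 1156 and 1411 for methoxychlor replicates 3 and 4. The 95% interval of the difference lay within 2-fold for 43.1% of probes, so larger differences were not excluded for the rest. Without DDE replicate 3, 1827 probes passed, and with array quality weights 4574 did.

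Against flutamide, DDE had UF_Msa_AF_108602 at least 10.95-fold lower with the chosen background treatment (limma adjusted p = 0.196; log2 fold change -5.18). With normexp the log2 fold change was -1.56, below that bound in size, so the bound does not hold for other treatments of background. By limma, 0 probes passed between DDE and flutamide, and 872 had an unadjusted p below 0.05, 664 of them higher in DDE. That direction was not settled, since 227 of 989 were higher with median scaling, 346 of 601 with quantile normalisation, 347 of 619 in the authors' value table and 88 of 197 with normexp. The count without 1 array was 314, 438, 3443 and 301 for DDE replicates 1, 2, 3 and 4, and 233, 2997 and 319 for flutamide replicates 2, 3 and 4. Array quality weights gave 4950 passing probes, with low weights for both DDE replicate 3 (0.244) and flutamide replicate 3 (0.348). Between methoxychlor and flutamide 0 passed by limma and 1061 had an unadjusted p below 0.05, 796 of them higher in methoxychlor. The direction depended on the scaling: 471 of 935 were higher with quantile normalisation, 527 of 900 with median scaling, 421 of 877 in the authors' value table and 3335 of 3409 with normexp. The count was 2492, 339 and 530 without methoxychlor replicates 2, 3 and 4, and 567 without flutamide replicate 2. With brightness as a covariate the count was 262. Between these groups 1321 passed on slide 2 alone, 1166 of them higher in methoxychlor, with the same 2 methoxychlor arrays. On slide 1 alone 0 passed, with 150 at an unadjusted p below 0.05, 76 higher, and with slide as a fixed or random block 0 passed. A moderated F test over the 4 groups passed 0 probes in limma, with 1039 at an unadjusted p below 0.05 and a smallest adjusted p of 0.428. Leaving out 1 array gave 467 (DDE replicate 4) to 3550 (DDE replicate 3) at an unadjusted p below 0.05. Brightness as a covariate gave 354. Array quality weights gave 4995 passing probes.

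Log2 fold changes against the shared controls correlated over 14007 probes, which are not independent replicates, at 0.17 for methoxychlor and DDE, 0.27 for methoxychlor and flutamide and 0.62 for DDE and flutamide. Unchanged groups were simulated by shuffling the residuals of all 16 arrays over the groups, so they shared simulated controls and not the real control arrays. They gave a median of 0.52, 0.51 and 0.51, and for DDE and flutamide a 95% range of -0.08 to 0.81. The covariances were 0.0325, 0.0407 and 0.142 beside simulated medians of 0.0737, 0.0774 and 0.0729. The simulated 95% range of the covariance for DDE and flutamide was -0.0114 to 0.227. With the controls split, 2 for each treatment, DDE and flutamide correlated at -0.03 to 0.31 over 6 splits, and methoxychlor and DDE at -0.51 to 0.26. Methoxychlor and flutamide then correlated at -0.49 to 0.28. Without flutamide replicate 3 the correlation of DDE and flutamide was 0.33, and on slide 2 alone 0.35. The other correlations moved more. For methoxychlor and DDE it was -0.22 with normexp, 0.81 on slide 1 alone and 0.06 on slide 2 alone. It was -0.02 and 0.07 without methoxychlor replicates 1 and 2, 0.37 and 0.27 without methoxychlor replicates 3 and 4, and 0.26, 0.29 and 0.41 without control replicates 2, 3 and 4. For methoxychlor and flutamide it was -0.25 with normexp and 0.73 on slide 1 alone. It was 0.17, 0.01 and 0.48 without methoxychlor replicates 1, 2 and 3, and 0.41 and 0.47 without control replicates 2 and 4. On a single slide the fold changes share only 2 control arrays. Unchanged groups were simulated for all 16 arrays only, so the single-slide correlations have no simulated values beside them.

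A set of 13 probes had a gap of at least 3 on the log2 scale between a high and a low set of arrays, with at least 3 arrays on each side. UF_Msa_AF_105791 and UF_Msa_CF_123090 were high on the same 4 arrays, 1 of each group. UF_Msa_AF_106338 and UF_Msa_CF_127156 were high on the same 6 arrays: 3 control, 1 methoxychlor and 2 flutamide. The smallest exact p across groups was 0.0286, for UF_Msa_CF_123486 (Fisher's exact test, adjusted p = 0.371 over the 13 probes).

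**Figure D3:**
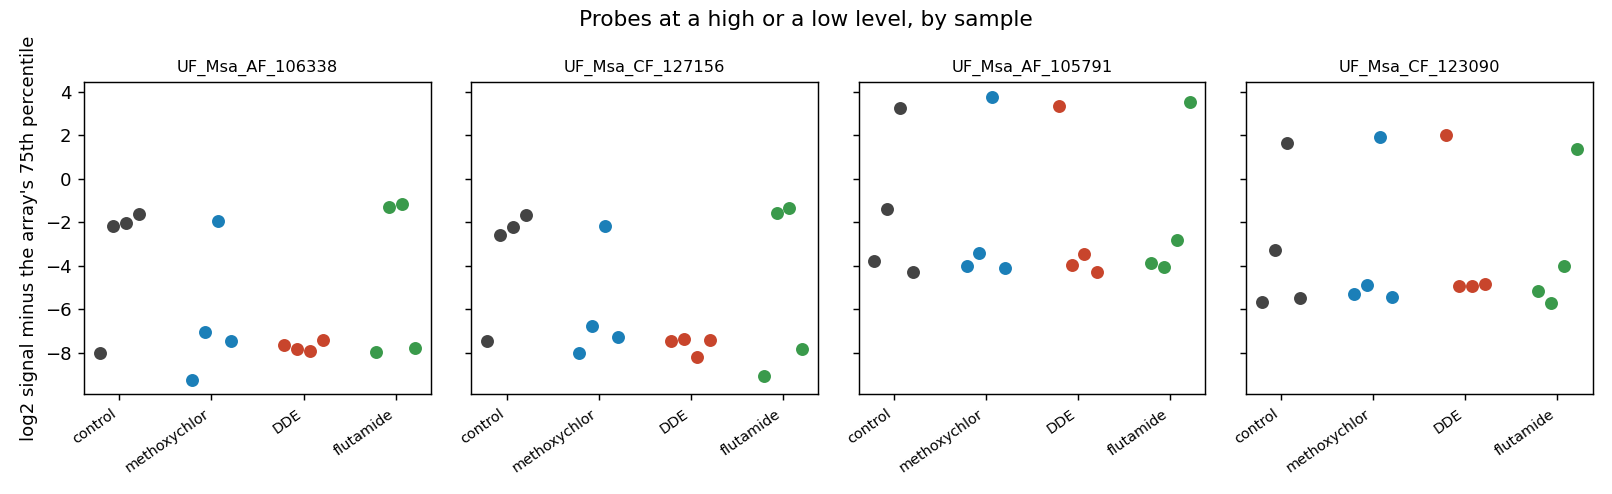
Log2 signal minus the array's 75th percentile is plotted for 4 probes, by group, with 1 point per array. UF_Msa_AF_106338 and UF_Msa_CF_127156 share 6 high arrays, and UF_Msa_AF_105791 and UF_Msa_CF_123090 share 4 high arrays.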

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

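The tests of array brightness, spike-in signal, slide, exchanged arrays and treatment below were chosen after the results were seen, as were the counts over other splits for the 3 treatments against control. The counts over other splits between treatments and over the 4 groups were written before those counts were seen.

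An array far from the other 3 of its group was found in 8 of 64 sets of 4 values. Chance gives about 1 in 20 for independent sets. These sets shared arrays and included probes picked for a small p, so 1 in 20 is not a fair yardstick for them. DDE replicate 3 scored 20.04 on the first axis, against -56.1 to -45.5 for the other DDE arrays. Flutamide replicate 3 scored -53.2, against -3.45 to 3.03. Single probes stood out in 6 cases. UF_Msa_CF_124455 read 0.20 in methoxychlor replicate 3 and UF_Msa_AF_106646 read -0.86 in methoxychlor replicate 2. UF_Msa_AF_102504 read -3.38 in DDE replicate 3, UF_Msa_CF_123486 read -0.27 in DDE replicate 2 and UF_Msa_AF_105185 read -1.28 in DDE replicate 1. UF_Msa_AD_200085 read -6.99 in flutamide replicate 4.

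Control spots outside the comparisons differed between arrays. The 14 bright corner spots averaged 14.18 on the log2 scale in DDE, above the highest control array at 13.28. The exact permutation p for DDE against control was 0.114 (adjusted p = 0.462 over 30 comparisons of array measures). These spots read 14.91, 14.55 and 15.08 on DDE replicates 1, 2 and 4 and 15.003 on flutamide replicate 3. All other arrays lay at 13.28 or below, DDE replicate 3 among them at 12.18.

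The arrays spread along a main axis that followed brightness. The tables argue against a bias that depends only on a probe's intensity as the whole source, since a smooth curve of mean level explained 10.08% of the variance of the loadings. Labelling or hybridisation yield is a candidate source, since the axis correlated with the spike-in signal at -0.81. That value passed a bound of 0.8 narrowly and fell to -0.68 without the 2 arrays farthest from the median. Treatment stays open as well, with a permutation p of 0.117 for the share of the axis that follows group.

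Probes passed for DDE against control when DDE replicate 3 was left out. The tables argue against slide as the source, since 102% of the median absolute log2 fold change of the 1114 probes remained with slide as a block and 859 still passed. With brightness as a covariate 60.004% remained: the median went from 1.22 (median SE 0.31) to 0.73 (SE 0.41) and 0 passed, so brightness and treatment cannot be told apart here, because the other DDE arrays are among the brightest. An exchange of DDE replicate 3 with flutamide replicate 3 may also be involved. This pair was picked for its place on the main axis. Among probes with small loadings on that axis, the 100 that best parted the other 3 DDE from the other 3 flutamide arrays were taken. On them DDE replicate 3 and flutamide replicate 3 were each nearer their own group for 7% of probes. The other 6 arrays gave 32% to 75%, with reference groups that held the arrays in doubt. Small loadings on the first axis do not remove the second. On the second axis flutamide replicate 3 scored -26.2, near DDE replicates 1, 2 and 4 at -35.3 to -28.9. DDE replicate 3 scored 29.4 there, among the other flutamide arrays at 16.7 to 46.4. The 7% may thus come from an array-wide difference on that axis, so it is no separate support for an exchange. Some probes went with the labels instead: UF_Msa_AF_108602 read -10.27 in DDE replicate 3 and -5.87 in flutamide replicate 3, UF_Msa_CF_123486 read -4.82 and -0.20, and UF_Msa_AF_105185 read -2.14 and -3.50, though these probes were picked with the given labels. Shared handling of the 4 arrays with high bright corner signal could also give such values, which was not tested, so the labels were kept.

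Chance was not excluded for any count at an unadjusted p below 0.05. For DDE against control 4 of the 35 splits of the 8 arrays gave at least 1776, the highest other 5145. The real split is included here and below. For DDE against methoxychlor 5 of 35 gave at least the real 2430, the highest other 5167. In both, every other split that reached the real count kept DDE replicates 1, 2 and 4 together. Each set DDE replicate 3 with the other group, in exchange for 1 array of that group. Such splits are near copies of the real groups, so these shares do not measure chance alone. The values were 22 of 35 for methoxychlor against control (real 332, highest other 3357), 10 of 35 for flutamide against control (real 735, highest other 1580), 10 of 35 for DDE against flutamide (real 872, highest other 6027) and 7 of 35 for methoxychlor against flutamide (real 1061, highest other 2614). Over the 4 groups 19 of 99 drawn splits gave at least the real 1039, or 20 of 100 with the real one, and the highest other was 4253. Several splits passed many probes at an adjusted p of 0.05 where the real groups passed 0, which points to a structure of the samples. The highest split of DDE and flutamide, which set DDE replicates 1, 2 and 4 and flutamide replicate 3 apart, passed 4805.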

How the results depend on the processing

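Of 166 counts of passing probes under alternatives, 151 were 0, as with the chosen settings. Brightness as a covariate, chosen after seeing the data, left all 7 counts at 0; at an unadjusted p below 0.05 it gave 430, 256 and 378 for methoxychlor, DDE and flutamide against control, 247, 760 and 262 for DDE against methoxychlor, DDE against flutamide and methoxychlor against flutamide, and 354 over the 4 groups. Array quality weights gave 4445 probes for DDE against control, 4574 for DDE against methoxychlor, 4950 for DDE against flutamide and 4995 over the 4 groups. The lowest weights were those of DDE replicate 3 (0.244), control replicate 2 (0.337) and flutamide replicate 3 (0.348). Slide 2 alone gave 801 for methoxychlor against control, 1321 for methoxychlor against flutamide and 1 for flutamide against control. It holds 1 DDE array, and slide 1 holds 1 flutamide array, whose spread was taken from the other groups. Fitting only the compared groups gave 1 for DDE against flutamide. Leaving out each replicate gave 0 to 1114 for DDE against control and 0 to 1827 for DDE against methoxychlor, with the highest values without DDE replicate 3. It gave 0 to 1 for flutamide against control, for DDE against flutamide and over the 4 groups, and 0 for both other comparisons. Correlations of fold changes moved too. With normexp they were -0.22 for methoxychlor and DDE and -0.25 for methoxychlor and flutamide. On slide 1 alone, where only 2 control arrays are shared, they were 0.81 and 0.73. For DDE and flutamide slide 2 alone gave 0.35. Leaving out each replicate gave -0.017 to 0.41, 0.013 to 0.48 and 0.33 to 0.74. Among 24 probe values, normexp reversed UF_Msa_CF_124914 in methoxychlor against control, from -1.19 to 0.82. In methoxychlor against flutamide it reversed UF_Msa_CF_127198 from -2.47 to 0.80 and UF_Msa_CF_123969 from -1.17 to 0.38. With the chosen settings both of the latter had a limma adjusted p of 0.591. Normexp also shrank others, UF_Msa_CF_121434 in DDE against flutamide from 1.54 to 0.09. Normexp moved the median log2 fold change of all probes to 0.40, -0.26 and -0.17 for methoxychlor, DDE and flutamide against control. Median scaling moved that of DDE to -0.20. The cause of these moves was not tested. Gene lists and panel genes were not run, since no probe has a gene name. No paired analysis was possible because the labels give no shared replicate numbers.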

Other observations

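All tests in this part were chosen after the results were seen. For the 13 probes at a high level in some samples and a low level in others, the area under the curve of brightness for high against low arrays ran from 0.179 to 0.778. The tables argue against array brightness as the whole source of the pattern, since in 12 of the 13 probes the best brightness boundary left at least 2 arrays on the wrong side. They argue against treatment as the whole source too, since in 12 of the 13 probes at least 2 arrays were on the other side from the rest of their group, or a group was evenly parted. In UF_Msa_CF_123486 there was 1 such array by each measure, so brightness and treatment stay open for it. A bound on the area tried first, 0.35 to 0.65 in every probe, was missed by 4 probes and had decided nothing on brightness. The tables argue against a sequence variant under a single probe for the 4 probes that shared their exact pattern with a probe of a different sequence with no 15 bases in common, since random patterns of the same sizes gave 0.0046 such probes on average. The random patterns were drawn separately for each probe, so variants inherited together under both probes of a pair were not excluded. For the other 9 probes a variant under a single probe stays open. A weaker relation to treatment is not excluded, with a smallest adjusted p of 0.371 across groups. A candidate explanation is that each pair of probes reads 1 transcript that differs in level between individual fish, and no gene name or genome was at hand to test it.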
